A study of Saccharomyces cerevisiae S288C with 71 samples.

How the data were processed

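The libraries came from Saccharomyces cerevisiae S288C cultures grown in a synthetic medium (yeast nitrogen base with ammonium and 2% glucose) at 30 C with shaking, per the labels' protocols. Cells were collected by vacuum filtration at 0, 12 and 16 h, the first of these in log phase. Libraries were made from polyadenylated RNA with a strand-specific kit after ribosomal RNA depletion and were sequenced on a HiSeq 4000, per the labels' protocols. The submitters' processing notes name Salmon 0.9.1, bcl2fastq 2.20.0.422 and the genome build sacCer3, without giving the role of each. How the annotation was built and how reads shared between near-identical genes were divided was not given in the sources used here.

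The deposited values are TPM, a length-corrected share of a library's transcripts that the authors had already scaled so that each library sums to the same total; the sums ran from 1000003 to 1000010. Values under 0.1 TPM stood at a floor of 0.1 in the deposited table, on average for 0.969% of the values of a library. The 2 deposited tables held identical contents, so 1 was used. TPM keeps no read count, so the sequencing depth of every library is unknown, no counting interval can be given, and precision was judged from the spread between libraries alone. Because TPM is a share of the library, a gene that takes a large share lowers the values of all others.

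The table held 5803 genes and 71 libraries in 36 groups of strain and time. Column names gave the strain and time but not the replicate, so libraries of a group were treated as unnumbered. The labels call the libraries of a group technical replicates. P-values therefore measure only the spread between such libraries and say nothing about the spread between separate cultures. In 35 groups there were 2 libraries, and cox4 rts1 at 16 h had 1, which was assumed to vary like the others. No pair of libraries held identical values.

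Genes with at least 1 TPM in at least 2 libraries were kept, which left 5766 and removed 37. Values were transformed as log2(TPM + 1), so fold changes are on that scale and understate the change of genes with low TPM. One limma model (version 3.58.1, R 4.3.3) with 1 mean per group was fitted over all libraries, with 35 residual degrees of freedom and empirical Bayes moderation with an intensity trend. Adjusted p-values are limma's, by the Benjamini-Hochberg method within each of 38 comparisons. A gene was taken as past the threshold, and is said to have risen or fallen, at an adjusted p under 0.05 and at least a 2-fold change. The comparisons set wild type at 12 and 16 h against 0 h, each single mutant against wild type and each double mutant against its electron transport chain single mutant at each time, and coq2 against cox4 at 16 h. An interaction term compared the change from 0 to 16 h in coq2 and in cox4 with that in wild type.

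Lists of genes by pathway, complex or cell type, 33 in all, were fixed before the data were examined, as were the comparisons, the tests, the thresholds and the rule for named genes. Each list with at least 5 measured members (31 lists) was tested against all other genes with limma's camera test, with the inter-gene correlation estimated from the residuals, and p-values were adjusted over the 1178 pairs of list and comparison. A preset correlation of 0.01 was an alternative. Which lists are described at which comparison was decided after their results were seen. Unless another number is given, the count of a list's members past the threshold adjusted over the list alone was the same as the count over all genes.

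Named genes followed a rule. The 5 deleted genes were read in every library and were not left out of the counts of genes past the threshold. For wild type at 16 h against 0 h, and for coq2 and cox4 against wild type at 16 h, the rule took the 8 largest rises and 8 largest falls past the threshold among genes with a standard name, at least 10 TPM on average in 1 of the groups and libraries that did not overlap between groups. The 3 largest of each were taken for the other 16 h comparisons. For a list, up to 4 members past the threshold with the largest change were named, with any member that went the other way. Names were matched to the R64 reference annotation, where 5779 of the 5803 identifiers were found, and coordinates are from that annotation. Named genes were searched against the R64 genome with blastn 2.17.0. Of 150 searched, 12 had another copy of at least 95% identity over at least 80% of their length and are treated as uncertain.

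The steps were tested on simulated data with 5766 genes, in which the coq2 mean at 16 h was set to the wild-type mean. At each fold size 50 genes were changed, and independent noise with each gene's fitted variance was added. The changed genes were drawn from those above a minimum wild-type level, so the rates below do not cover genes with low TPM. At 1.5-fold 0 of 50 passed the threshold, at 2-fold 23, at 3-fold 49 and at 4-fold 50, with 2 unchanged genes called. By adjusted p alone 38, 49, 49 and 50 were found, with 8 unchanged genes called. None of the 31 lists was called, but the noise held no correlation between genes, so this does not test the list calls in the real data. Genes changed by close to 2-fold were thus often missed by the threshold in that comparison.

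Alternatives were a pseudocount of 0.1 or 5, no expression filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, a fit on the time point alone, no intensity trend, and each library left out in turn. Leaving out CUP1-1, and leaving out a cox4 tco89 library that held COX4 transcripts, were added after the data were seen. Where median-ratio scaling moved the balance of higher and lower calls by over 10 percentage points, that split is given beside the main one. The shift given with it is the median over genes of the log2 fold change on the deposited scale minus that with median-ratio scaling. Simulations with no effect, 100 for each, give the overlap that shared control libraries make through the spread between technical replicates, not through differences between cultures. Others, added after the data were seen, dealt each strain's estimated effects out at random over genes. List tests on the time point alone used the 24 or 23 libraries of that time (12 or 11 residual degrees of freedom), for wt over time its 6 libraries (3), and for the interactions 12 libraries (6). Reads were not used here.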

Results

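RNA abundance was measured in 12 strains of S. cerevisiae S288C at 3 times, 0, 12 and 16 h, across the diauxic shift of the wild type, when cells pass from fermenting glucose to respiring its products. The strains were the wild type (wt), 2 electron transport chain mutants (coq2, which lacks an enzyme of coenzyme Q synthesis, and cox4, which lacks a subunit of cytochrome c oxidase), 3 mutants described in the labels as suppressors of the death of such mutants on starvation, and the 6 double mutants. The suppressors lacked RAS2, a small GTPase upstream of adenylate cyclase, RTS1, a regulatory subunit of protein phosphatase 2A, or TCO89, a subunit of TORC1. There were 71 libraries, 2 in each of 35 groups and 1 of cox4 rts1 at 16 h, and values are mean TPM ± SD with n = 2 unless stated. Each library held at least 1 TPM for 5622 to 5699 genes. Libraries of a group correlated across genes at r = 0.985 to 0.998, and 5 to 109 genes differed by over 2-fold between them.

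The deleted genes were low in the strains that lacked them. COQ2 (YNR041C, chromosome XIV, 700541 to 701659) stood at 0.1 to 2.95 TPM in the 24 libraries of strains without it and at 5.55 to 60.2 TPM in the other 47. RAS2 (YNL098C, chromosome XIV, 439602 to 440570) ranged from 0.1 to 2.32 TPM in 18 libraries against 67.1 to 255 TPM. RTS1 (YOR014W, chromosome XV, 357674 to 359947) ranged from 0.1 to 1.97 TPM in 17 libraries against 18.9 to 54.8 TPM, and TCO89 (YPL180W, chromosome XVI, 205248 to 207647) from 0.1 to 1.36 TPM in 18 libraries against 6.29 to 20.8 TPM. COX4 (YGL187C, chromosome VII, 149704 to 150171) ranged from 0.115 to 72.3 TPM in 23 libraries against 283 to 3460 TPM in 48. The highest of these values, 72.3 TPM, was in 1 of the cox4 tco89 libraries at 16 h, and the other library of that group held 2.95 TPM. COX4 also stood at 10.8 against 2.46 TPM in the cox4 libraries at 16 h, and at 8.57 TPM in the only cox4 rts1 library of that time. In wt it then held 1280 and 1260 TPM. Smaller amounts of deleted genes stood in 1 library of some groups at 12 h. A coq2 rts1 library held COQ2 at 2.95 and RTS1 at 1.97 TPM, against 0.1 TPM for both in the other library. COQ2 stood at 2.27 against 0.1 TPM in coq2, where wt at 12 h held 10.9 and 11 TPM. RTS1 stood at 1.76 against 0.115 TPM in rts1, and TCO89 at 1.36 against 0.1 TPM in tco89. Whether any of these libraries holds RNA of another strain was not analysed here. Transcripts of the mating-type alpha genes were high at 0 h (MF(ALPHA)1, median 4050 TPM over libraries), and those of a-cell genes such as STE2 (median 6.79 TPM) were low.

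Between 0 and 16 h wild-type cells turned up genes of respiration, growth on nonfermentable carbon and stress, and turned down genes of translation and glycolysis. All 12 genes of the glyoxylate cycle and gluconeogenesis rose (camera adjusted p = 0.0044, or 0.2 with a fit on wt libraries alone). The lactate carrier gene JEN1 went from 4.39 ± 0.378 to 1040 ± 42.7 TPM, malate synthase MLS1 (YNL117W, chromosome XIV, 406358 to 408022) from 3.3 ± 0.84 to 535 ± 12.3 TPM, the succinate-fumarate carrier SFC1 from 0.754 ± 0.266 to 395 ± 11.6 TPM, and the gluconeogenic enzyme PCK1 (YKR097W, chromosome XI, 631152 to 632801) from 6.36 ± 0.567 to 391 ± 12.3 TPM. Of the 11 genes of respiratory complex III and cytochrome c, 10 rose (adjusted p = 0.016, or 0.3 on wt alone), with CYC7 up 36.5-fold and QCR10, QCR8 and QCR7 up 11.2-, 11.2- and 8.73-fold. That list, with the cytochrome c genes CYC1 and CYC7 in it, is called complex III for short below. Each of the 8 cytochrome c oxidase genes rose (adjusted p = 0.045, or 0.23 on wt alone), among them COX7 (11.5-fold), COX5A (8.23-fold), COX13 (7.09-fold) and COX9 (6.15-fold). Beta-oxidation and peroxisome genes rose in 12 of 17 cases (adjusted p = 0.029, or 0.36 on wt alone), led by the carnitine system genes CRC1, CAT2 and YAT2 at 33-, 24.1- and 18.3-fold, and SPS19 at 12.5-fold.

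General stress response genes rose in 33 of 34 cases in the wild type (adjusted p = 0.0051, or 0.1 on wt alone). The hydrophilin genes SIP18 (YMR175W, chromosome XIII, 611016 to 611255) and GRE1 reached 29000 ± 2670 and 6010 ± 253 TPM from 10.3 ± 0.514 and 16 ± 0.0605 TPM, SPI1 reached 16200 ± 992 TPM and the small heat shock gene HSP26 19300 ± 180 TPM. The other largest rises were in the stationary phase genes SPG4 (894-fold) and SPG1 (546-fold), the membrane heat shock gene HSP30 (719-fold) and the hexose transporter gene HXT6 (329-fold), with adjusted p of 4.1e-22 or smaller for all 8. HXT6 and HXT7 are near copies of each other (99.8% identity), so the division of their reads is uncertain. Hexose transport genes went both ways, 7 of 16 up and 3 down (adjusted p = 0.5). HXT5 rose 81.3-fold and HXT7 17.4-fold, and the low-affinity transporter gene HXT1 fell from 333 ± 23.1 to 9.06 ± 0.39 TPM.

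Cytosolic ribosomal protein genes fell in 130 of 133 cases between 0 and 16 h, for example RPL9A (27.7-fold), RPS22A (23.9-fold), RPL22A (14.7-fold) and RPS26B (12.9-fold). Ribosome biogenesis genes fell in 78 of 89 cases, including NOP1 (34-fold), DBP2 (22.6-fold), NOP58 (15.3-fold) and RPA49 (15.2-fold). In glycolysis and fermentation 15 of 19 genes fell, with ENO2 (YHR174W, chromosome VIII, 451327 to 452640) going from 8080 ± 85.8 to 190 ± 22.1 TPM, TDH2 falling 25.3-fold and HXK2 14.5-fold. PDC6, a minor pyruvate decarboxylase, rose 36.2-fold against the rest of that list, and TDH1 also rose (log2 2.48). Against all other genes these 3 lists did not stand apart with an estimated correlation (adjusted p = 0.24, 0.33 and 0.51). TDH2 is 95.8% identical to TDH3 and uncertain to that extent. Other large falls were in the ammonium and amino acid permease genes MEP2 (36.2-fold) and GAP1 (42-fold), the transcription factor gene SFG1 (34.5-fold), the cell wall gene UTR2 (32.2-fold) and the pheromone gene MF(ALPHA)2 (28.3-fold).

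In all, 1018 genes rose and 1666 fell in the wild type from 0 to 16 h. With median-ratio scaling 1325 rose and 1264 fell (shift of the deposited scale against it -0.30 log2). At 12 h against 0 h the counts were 1018 and 1598, or 1294 and 1261 with that scaling (shift -0.27). By 12 h the glyoxylate and gluconeogenesis list (11 of 12 up, adjusted p = 0.0089, or 0.22 on wt alone), complex III and cytochrome c (9 of 11, adjusted p = 0.017, or 0.3 on wt alone), cytochrome c oxidase (8 of 8, adjusted p = 0.039, or 0.22 on wt alone) and the general stress list (33 of 34, adjusted p = 0.0051, or 0.1 on wt alone) had risen. Beta-oxidation genes rose in 13 of 17 cases (adjusted p = 0.034, or 0.37 on wt alone), and DCI1 fell (log2 -1.39).

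**Figure D1:**
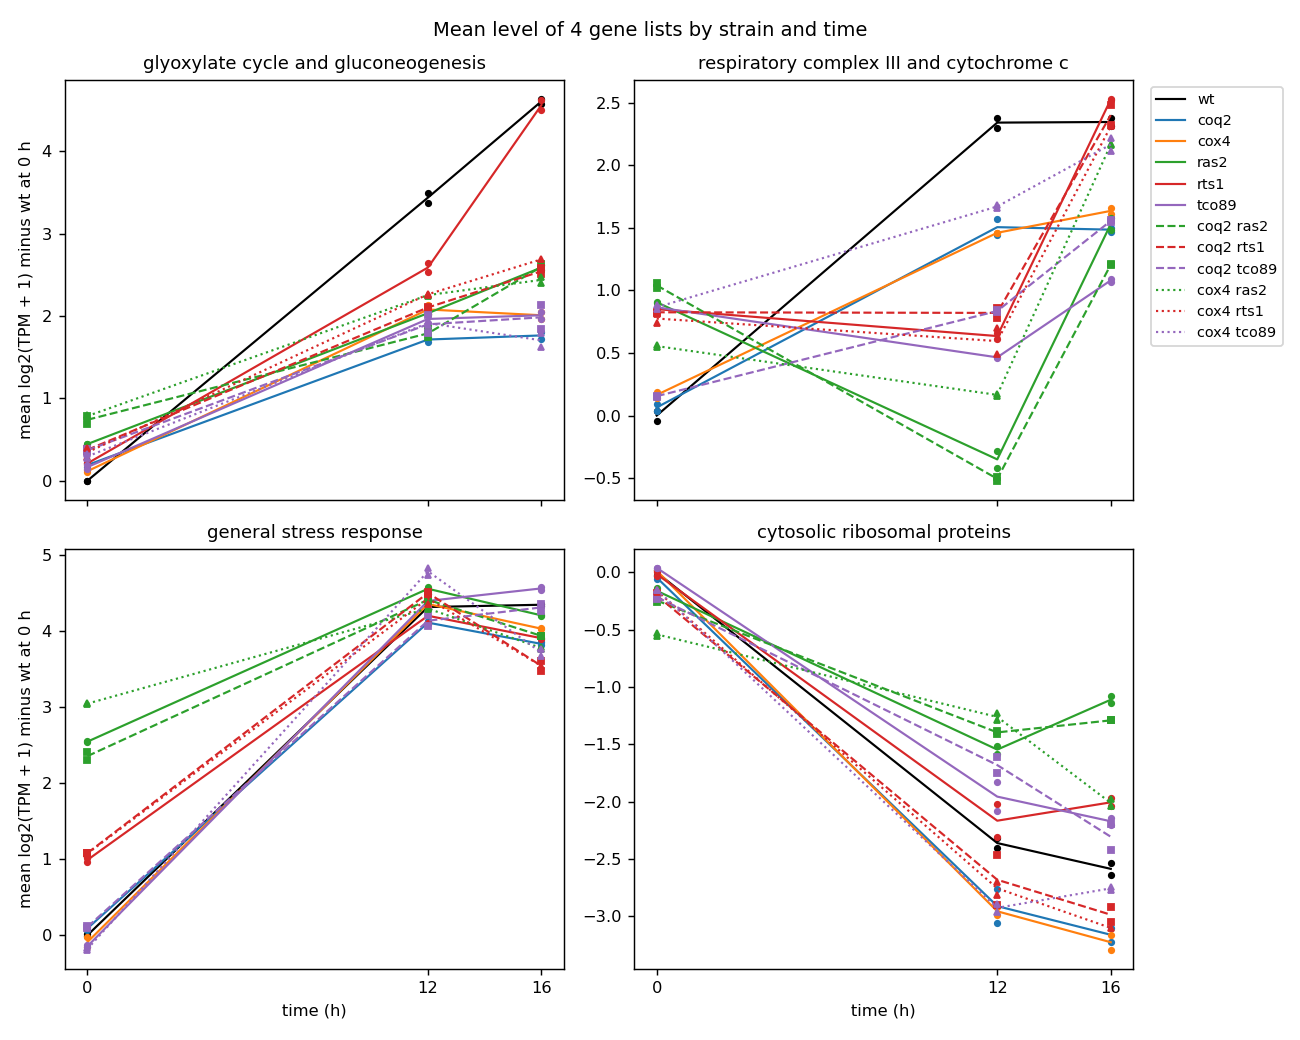
Mean log2(TPM + 1) of the genes of 4 lists, minus its value in wild type at 0 h, plotted against time in hours for the 12 strains, with points for libraries and lines through group means. The glyoxylate and gluconeogenesis genes of wild type and rts1 reached 4.61 and 4.56 at 16 h, above the 1.71 to 2.69 of the other 10 strains.

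In coq2 cells the genes of growth on nonfermentable carbon stayed far below their wild-type level at 16 h. Of the 12 glyoxylate and gluconeogenesis genes 11 were lower (adjusted p = 0.0025, or 0.095 on the 16 h libraries alone), with isocitrate lyase ICL1 (YER065C, chromosome V, 285241 to 286914) at 41.8 ± 2.34 against 1060 ± 6.42 TPM, SFC1 at 11.9 ± 0.515 against 395 ± 11.6, MLS1 at 24.8 ± 0.423 against 535 ± 12.3 and fructose bisphosphatase FBP1 at 39.6 ± 3.72 against 559 ± 46.8 TPM. Of 15 TCA cycle genes 11 were lower (adjusted p = 0.023, or 0.17 on 16 h alone), with aconitase ACO1 down 6.76-fold, IDH2 4.35-fold, CIT1 4.31-fold and IDH1 3.29-fold. Fewer of these lists' members passed with median-ratio scaling, 10 and 7. ATP synthase genes were lower in 11 of 13 cases (ATP14 and ATP7 each 3.38-fold, ATP20 3.32-fold, ATP1 3.23-fold) and mitochondrial ribosomal protein genes in 34 of 53 (MRPL20 3.76-fold, MRPL3 3.73-fold, MRPL35 3.33-fold, MRPL11 3.32-fold). These last lists missed the threshold with an estimated correlation (adjusted p = 0.079 and 0.095), and 5 and 16 of their genes were lower with median-ratio scaling.

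The largest falls in coq2 at 16 h also took in ECM13, from 575 ± 20.5 in wild type to 10.5 ± 2.54 TPM, the cytosolic isocitrate dehydrogenase gene IDP2 (12.6-fold), PCK1 (11.1-fold) and JEN1 (10-fold). The 8 largest falls had adjusted p of 7.7e-24 or smaller and standard errors of 0.12 to 0.18 log2. Among the rises, the metallothionein gene CUP1-1 (YHR053C, chromosome VIII, 212535 to 212720) went from 57200 ± 3570 to 186000 ± 10900 TPM (3.26-fold, adjusted p = 4.6e-17). CUP1-1 has an identical copy beside it, CUP1-2, and the value may hold reads of both. RRT15, a small gene next to the ribosomal DNA (YLR162W-A, chromosome XII, 490406 to 490594), rose from 931 ± 33 to 9850 ± 233 TPM (adjusted p = 1.8e-06). The cell wall genes SCW4 and CIS3 rose 3.58- and 3.21-fold, the sodium-phosphate transporter gene PHO89 3.03-fold, BTN2 2.98-fold and ZPS1 2.95-fold. FLP1, the recombinase of the 2-micron plasmid, rose 2.77-fold and was not found in the reference annotation by that name.

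At 16 h 78 genes were higher and 712 lower in coq2 than in wt. With median-ratio scaling 308 were higher and 188 lower (shift of the deposited scale against it -0.41 log2), so the balance between rises and falls depended on the scaling. At 12 h 17 were higher and 252 lower (59 and 88 with that scaling, shift -0.307), and without 1 of the coq2 libraries the total at 12 h was 440, against 212 without the other. The glyoxylate list (9 of 12 lower, adjusted p = 0.0023) and the TCA cycle (8 of 15 lower, adjusted p = 0.0034) were already down by then, with ICL1 lower by 10.1-fold, SFC1 by 6.5-fold, MLS1 by 6.28-fold and ACO1 by 3.58-fold. ATP synthase (4 of 13 lower, adjusted p = 0.039, or 0.19 on the 12 h libraries alone) and complex III (2 of 11 lower, adjusted p = 0.02, or 0.14 on 12 h alone) were lower to a smaller extent, and with median-ratio scaling 0 and 1 of their genes passed. At 0 h only 7 genes were higher and 9 lower. The iron uptake list was lower at that time (adjusted p = 0.0047), although ARN2 (66.2 ± 1.44 against 162 ± 0.983 TPM) was the only 1 of its 19 genes past the threshold. The phosphate starvation list was lower too (adjusted p = 0.0051, that on the 0 h libraries alone not being given here). Of its 17 genes 1 passed the threshold, or 2 when adjusted over the list alone, and 0 with median-ratio scaling.

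In cox4 cells the same lists were lower at 16 h. The glyoxylate list was lower in 10 of 12 cases (adjusted p = 0.0033, or 0.099 on the 16 h libraries alone), with ICL1 at 45.8 ± 0.735 TPM (22.8-fold below wt), SFC1 at 14.9 ± 1.3 (25-fold), FBP1 at 45 ± 3.12 (12.2-fold) and MLS1 at 48.3 ± 3.4 TPM (10.9-fold). TCA cycle genes were lower in 10 of 15 cases (adjusted p = 0.022, or 0.16 on 16 h alone), among them ACO1 (6.38-fold), CIT1 and IDH2 (each 4.06-fold) and IDH1 (2.88-fold). ATP synthase genes were lower in 11 of 13 cases (ATP20 3.14-fold, ATP7 3.04-fold, ATP1 2.97-fold, ATP14 2.77-fold) and mitochondrial ribosomal protein genes in 21 of 53 (MRPL20 3.3-fold, MRPL32 3.07-fold, MRPL3 3.02-fold, MRP13 2.93-fold), with adjusted p = 0.066 and 0.13 with an estimated correlation. With median-ratio scaling 10 glyoxylate, 5 TCA cycle, 5 ATP synthase and 14 mitochondrial ribosomal protein genes were lower.

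Other large falls in cox4 at 16 h were in ECM13 (39.7-fold), IDP2 (10.4-fold), PCK1 (9.73-fold) and SIP4, a transcriptional activator of gluconeogenic genes (9.27-fold). The rises were led by the hexose transporter gene HXT13 (YEL069C, chromosome V, 21537 to 23231), from 1.27 ± 0.171 to 17.2 ± 0.764 TPM, and its neighbour DSF1, a mannitol dehydrogenase (YEL070W, chromosome V, 19589 to 21097), from 45.1 ± 7.24 to 230 ± 6.2 TPM. Both have near copies elsewhere (HXT17, 97.2%, and MAN2, 98.9%) and are uncertain. PHO89 rose 4.12-fold, SCW4 3.81-fold, CIS3 3.76-fold, invertase SUC2 3.62-fold, ZPS1 3.6-fold and BTN2 3.51-fold. Adjusted p was 4.6e-08 or smaller for all 8 rises. At 16 h 115 genes were higher and 549 lower (298 and 203 with median-ratio scaling, shift -0.302).

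At 12 h 48 genes were higher and 140 lower in cox4 (72 and 77 with median-ratio scaling, shift -0.145). Hexose transport genes were higher in 4 of 16 cases (adjusted p = 0.029, or 0.067 on 12 h alone): HXT13 by 30.4-fold, HXT17 by 3.15-fold, HXT7 by 2.61-fold and HXT2 by 2.4-fold, of which HXT17 fell short of 2-fold with a pseudocount of 5. Lower at 12 h were TCA cycle (9 of 15, 6 with median-ratio scaling, adjusted p = 0.0031), glyoxylate (7 of 12, adjusted p = 0.0052, or 0.062 on the 12 h libraries alone), complex III (4 of 11, 2 with that scaling, adjusted p = 0.0039, or 0.078 on 12 h alone) and ATP synthase genes (11 of 13, adjusted p = 0.0066, or 0.1 on 12 h alone, with 3 under that scaling). At 0 h iron uptake genes stood out, with 12 of 19 lower (adjusted p = 1.2e-06). The cell wall mannoprotein genes FIT3 (YOR383C, chromosome XV, 1060441 to 1061055) and FIT2 stood at 86.3 ± 8.78 against 1080 ± 117 and 372 ± 35.9 against 2500 ± 292 TPM, the siderophore transporter gene ARN2 at 22.1 ± 0.936 against 162 ± 0.983 and TIS11 at 27.7 ± 1.88 against 174 ± 6.5 TPM. In total 15 genes were higher and 33 lower at 0 h.

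The coq2 and cox4 profiles at 16 h differed little from each other. Only 4 genes were higher and 17 lower in coq2 than in cox4 (6 and 14 with median-ratio scaling, shift -0.109). The deleted genes were not left out of these counts. COX4 stood at 780 and 819 TPM in coq2 against 10.8 and 2.46 in cox4, and COQ2 at 0.1 and 0.1 against 10.1 and 9.23 TPM. HXT13 was 8.45-fold, DSF1 4.45-fold and the phosphatase subunit gene REG2 2.51-fold lower in coq2. RRT15 was 5.24-fold higher (adjusted p = 0.0075), a call lost with quantile normalization (log2 1.43) or without 1 of the coq2 or 1 of the cox4 libraries (log2 2.41 and 2.28). MVD1, of the mevalonate pathway, was 2.12-fold higher and fell short of 2-fold without 1 of the coq2 libraries (log2 0.96). MVD1 (YNR043W, chromosome XIV, 701895 to 703085) lies beside COQ2, so the deletion itself may affect its level. Against wt, 49 genes were higher and 447 lower in both mutants, and 0 went opposite ways. Independent lists of those sizes would share 1.56 and 67.8 genes. Simulated groups with no effect against the same wt libraries shared 0, which follows from their having almost no calls. Fold changes correlated across genes at r = 0.907, against 0.504 in the simulation, with a covariance of 0.332 against 0.0142. Genes are not independent replicates, and part of the overlap may come from the shared wt libraries. The simulated noise was the spread between technical replicates, so it leaves out any deviation of the wt culture at 16 h from other wt cultures. How much overlap such a deviation makes cannot be told from these data.

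The change from 0 to 16 h differed from that of wt for 816 genes in coq2 (110 higher and 706 lower) and for 756 in cox4 (160 and 596). With median-ratio scaling these were 321 and 234 (shift -0.367), and 306 and 305 (shift -0.237). The glyoxylate list rose less in both, for 11 of 12 genes each (adjusted p = 0.00024 and 0.00057, or 0.067 and 0.096 on the libraries of wt and that mutant alone), as did the TCA cycle (11 and 9 of 15, adjusted p = 0.012 and 0.011, or 0.24 and 0.25) and mitochondrial ribosomal protein genes (37 and 34 of 53, adjusted p = 0.045 and 0.038, or 0.097 and 0.15). With median-ratio scaling 6 and 6 TCA cycle and 19 and 20 mitochondrial ribosomal protein genes passed. In cox4 8 of 19 iron uptake genes rose more than in wt (adjusted p = 0.043, or 0.19). They started lower, with 12 of the 19 below wt at 0 h. At 16 h 1 of the 19 was higher and 8 were lower in cox4 than in wt (2 and 3 with median-ratio scaling).

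In ras2 stress genes were higher and iron uptake genes lower than in wt in log phase. At 0 h 29 of 34 general stress genes were higher than in wt (adjusted p = 1e-05), with HSP12 at 14000 ± 733 against 433 ± 9.34 TPM, SIP18 at 287 ± 30 against 10.3 ± 0.514, DDR2 at 4950 ± 234 against 221 ± 5.67 and GND2 at 130 ± 0.629 against 5.51 ± 0.778 TPM. Of 18 trehalose and glycogen genes 10 were higher (adjusted p = 0.0039, or 0.11 on the 0 h libraries alone), among them glycogen phosphorylase GPH1 (13.4-fold), PGM2 (7.2-fold), TSL1 (5.85-fold) and GDB1 (4.55-fold). Iron uptake genes were lower in 15 of 19 cases (adjusted p = 0.00051), led by FIT3 (17.2-fold), FIT2 (15.7-fold), TIS11 (13.4-fold) and ARN2 (12.7-fold). Phosphate starvation genes were lower in 8 of 17 cases and PHM8 was higher (adjusted p = 0.019), and 4 of 11 complex III genes were higher (2 with quantile normalization, adjusted p = 0.0034). Altogether 207 genes were higher and 72 lower.

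At 12 h the ras2 strain held high glycolytic and low respiratory transcripts. Each of the 11 complex III and cytochrome c genes was lower (adjusted p = 0.00057), with CYC1 at 32.4 ± 13 against 457 ± 23.1 TPM, QCR7 lower by 9.7-fold, QCR8 by 9.1-fold and QCR6 by 7.91-fold. Cytochrome c oxidase (7 of 8, adjusted p = 0.019, or 0.17 on 12 h alone), ATP synthase (13 of 13, adjusted p = 0.019, or 0.14) and TCA cycle genes (10 of 15, adjusted p = 0.039, or 0.12 on the 12 h libraries alone) were lower too. Glycolytic and fermentation genes were higher in 16 of 19 cases, though not against other genes (adjusted p = 0.059), with PGK1 (YCR012W, chromosome III, 137746 to 138996) at 6420 ± 369 against 684 ± 105 TPM, ENO1 9.14-fold, PDC6 9.12-fold and TPI1 7.77-fold higher. In all 289 genes were higher and 684 lower (449 and 477 with median-ratio scaling, shift -0.192). At 16 h 9 of 12 glyoxylate genes were lower (adjusted p = 0.0067, or 0.11 on the 16 h libraries alone), with FBP1, SFC1, PCK1 and ICL1 lower by 15.3-, 13-, 10.4- and 9.23-fold, and 5 of 11 complex III genes were lower (8 with quantile normalization, adjusted p = 0.045, or 0.12 on 16 h alone). Cytosolic ribosomal protein genes were higher in 115 of 133 cases (RPS22A 6.12-fold, RPL43B 4.88-fold, RPL26B 4.83-fold, RPS13 4.8-fold), with adjusted p = 0.068 against other genes. The glucose-responsive hexose transporter gene HXT4 rose from 59.8 ± 6.54 to 950 ± 28.1 TPM, the dihydroxyacetone kinase gene DAK2 8.98-fold and PGK1 6.35-fold. At 16 h 425 genes were higher and 447 lower.

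In rts1 some of the same lists differed from wt in log phase, with smaller folds for the stress genes. At 0 h 17 of 34 general stress genes were higher (adjusted p = 0.0003), HSP12 by 9.88-fold, DDR2 by 4.5-fold, HXK1 by 3.94-fold and CTT1 by 3.85-fold. Iron uptake genes were lower in 12 of 19 cases (adjusted p = 0.0023, or 0.057 on the 0 h libraries alone), with FIT3 at 148 ± 6.8 and FIT2 at 386 ± 9.19 TPM, ARN2 lower by 6.7-fold and TIS11 by 4.6-fold. Genes under nitrogen catabolite repression were lower in 11 of 23 cases (adjusted p = 0.029, or 0.076 on 0 h alone): the GATA repressor gene DAL80 stood at 1.12 ± 0.183 against 184 ± 2.76 TPM, MEP2 at 64.6 ± 1.67 against 1510 ± 42.4, DAL5 at 9.31 ± 0.675 against 129 ± 13.4 and PUT1 at 6.59 ± 0.0871 against 57 ± 1.97 TPM. OPT2 was higher, against the rest of that list (log2 2.60). Phosphate starvation genes were lower in 7 of 17 cases (adjusted p = 0.0071), and 4 of 18 trehalose and glycogen (adjusted p = 0.022, or 0.18 on 0 h alone), 4 of 11 complex III (adjusted p = 0.00014) and 3 of 15 TCA cycle genes (adjusted p = 0.047) were higher. At this time 81 genes were higher and 74 lower (111 and 58 with median-ratio scaling, shift -0.153).

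At 12 h glycolysis and fermentation genes were higher in rts1 than in wt in 17 of 19 cases (adjusted p = 0.02, or 0.095 on the 12 h libraries alone). PGK1 stood at 9990 ± 971 against 684 ± 105 TPM, ENO1 at 15600 ± 1370 against 1260 ± 172, TDH2 at 1380 ± 189 against 148 ± 23.3 and ENO2 at 1980 ± 545 against 216 ± 62.8 TPM. Complex III genes were lower in 10 of 11 cases (adjusted p = 0.0069, or 0.1 on 12 h alone), with QCR8, QCR2, QCR7 and CYC7 lower by 6.66-, 4.31-, 3.86- and 3.5-fold, and cytochrome c oxidase genes in 8 of 8 (adjusted p = 0.048, or 0.22 on 12 h alone, with 5 genes past the threshold under median-ratio scaling). Altogether 225 genes were higher and 819 lower (478 and 375 with that scaling, shift -0.344). By 16 h no list passed, although 16 of 19 glycolytic genes were higher (adjusted p = 0.12), PGK1 by 6.12-fold, ENO1 by 4.95-fold, TDH3 by 4.28-fold and TDH2 by 4.14-fold, and PYK2 was lower (log2 -1.08). TCA cycle genes were higher in 5 of 15 cases (4 with median-ratio scaling) and lower in 0. The 6-phosphofructo-2-kinase gene PFK27 rose 7.93-fold and the plasma membrane proteolipid gene PMP2 5.23-fold, whereas acetaldehyde dehydrogenase ALD6 fell 6.68-fold and glycerol kinase GUT1 5.3-fold. At 16 h 378 genes were higher and 261 lower (277 and 332 with median-ratio scaling, shift 0.11). The mean log2 level of the glyoxylate list, relative to wt at 0 h, was 2.59 at 12 h against 3.44 in wt, and 4.56 at 16 h against 4.61.

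The single tco89 strain had low iron uptake transcripts at 0 h. Of the 19 genes 14 were lower than in wt (adjusted p = 1.3e-07), with FIT2 at 45.3 ± 3.5 against 2500 ± 292 TPM, FIT3 at 34 ± 2.79 against 1080 ± 117, TIS11 at 8.09 ± 0.421 and ARN2 at 10.7 ± 0.363 TPM. Genes under nitrogen catabolite repression were lower in 10 of 23 cases (adjusted p = 0.0015), and in 11 when adjusted over the list alone, with DAL80 4.89-fold, PUT1 3.81-fold and DAL5 3.48-fold lower. ASP3-1, also 3.09-fold lower, has 3 identical copies and is uncertain. Phosphate starvation genes were lower in 5 of 17 cases (adjusted p = 0.00024). Complex III genes were higher in 4 of 11 cases (3 with median-ratio scaling, 2 with quantile normalization, adjusted p = 1e-05). These were QCR8 by 2.18-fold, RIP1 by 2.08-fold, CYC1 by 2.07-fold and QCR10 by 2.03-fold. Of these 4, all but QCR8 fell short of 2-fold with quantile normalization, and QCR10 also with median-ratio scaling (log2 0.97). Cytochrome c oxidase (2 of 8, 0 with quantile normalization, adjusted p = 0.009, or 0.1 on the 0 h libraries alone), ATP synthase (1 of 13, adjusted p = 0.0018) and TCA cycle genes (3 of 15, adjusted p = 0.0064) were higher as lists. At 0 h 31 genes were higher and 62 lower.

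At 12 h each of the 11 complex III genes was lower in tco89 (adjusted p = 0.00014), with QCR8, QCR7, QCR9 and CYC7 lower by 6.07-, 5.06-, 4.75- and 4.35-fold. Glyoxylate genes were lower in 7 of 12 cases (adjusted p = 0.017, or 0.082 on the 12 h libraries alone) and TCA cycle genes in 10 of 15 (adjusted p = 0.018, or 0.088 on 12 h alone), and LSC1 of the latter was higher (log2 1.00). Glycolytic genes were higher in 17 of 19 cases (adjusted p = 0.088), PDC1 by 6.89-fold, TDH2 by 6.56-fold, ENO1 by 6.32-fold and PGK1 by 6.2-fold. At this time 408 genes were higher and 282 lower (281 and 371 with median-ratio scaling, shift 0.145). By 16 h the glyoxylate list was lower in 9 of 12 cases (adjusted p = 0.00037), with ICL1 at 39.1 ± 3.7, FBP1 at 21.9 ± 0.00742, PCK1 at 22.6 ± 2.48 and SFC1 at 27.9 ± 2.78 TPM. Complex III (9 of 11, adjusted p = 0.00054), ATP synthase (8 of 13, adjusted p = 0.011), TCA cycle (6 of 15, adjusted p = 0.023, or 0.13 on the 16 h libraries alone), cytochrome c oxidase (3 of 8, adjusted p = 0.033) and mitochondrial ribosomal protein genes (10 of 53, 22 with median-ratio scaling, adjusted p = 0.039, or 0.11 on 16 h alone) were lower. Glycolytic genes were higher in 17 of 19 cases (adjusted p = 0.12), 16 of which were also higher at 12 h, with PDC6 higher only at 12 h and PFK1 only at 16 h. Among the 17 were PGK1 (5.31-fold), HXK2 (5.25-fold), TPI1 (5.17-fold) and ENO1 (4.76-fold). DAK2 rose from 13 ± 0.563 to 739 ± 131 TPM and the transporter genes HXT3 and HXT4 26.1- and 13.5-fold. At 16 h 323 genes were higher and 254 lower (199 and 359 with median-ratio scaling, shift 0.162). HMRA2 was listed at the 0.1 TPM floor in ras2, rts1 and tco89 at 16 h against 29.1 ± 21.6 TPM in wt. It shares its sequence with the other mating-type loci, and those calls were lost without 1 of the wt libraries (log2 -3.76), so its level is uncertain.

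In coq2 ras2 stress genes were higher than in coq2 at 0 h and ribosomal genes later. At 0 h 29 of 34 general stress genes were higher than in coq2 (adjusted p = 1e-05), with HSP12 at 14300 ± 195 against 884 ± 25.2 TPM, SIP18 19.6-fold, CTT1 15.2-fold and DDR2 13-fold higher, and 13 of 19 iron uptake genes were lower (adjusted p = 0.00057). At 12 h complex III genes were lower in 10 of 11 cases (adjusted p = 0.00073) and cytochrome c oxidase genes in 7 of 8 (adjusted p = 0.019, or 0.16 on the 12 h libraries alone). At 16 h 127 of 133 cytosolic ribosomal protein genes were higher (RPL43B 9.5-fold, RPL4B 7.83-fold, RPS9A 6.78-fold, RPS26B 6.68-fold), as were 69 of 89 ribosome biogenesis genes (NSR1 8.65-fold, RRS1 7.67-fold, RPA49 7.27-fold, MAK16 6.9-fold), and NOP16 (log2 -1.47) and RRP14 (log2 -1.71) fell. Neither list stood apart from all other genes (adjusted p = 0.18 and 0.38). RPL4B is 99.3% identical to RPL4A and uncertain.

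The largest rises in coq2 ras2 over coq2 at 16 h were in the biotin transporter gene VHT1, from 24 ± 4.17 to 425 ± 25.3 TPM, PDC6 (14-fold) and HXT13 (10.3-fold), and large falls were in NGL3 (14.6-fold) and the RNA-binding protein gene NPL3 (12.2-fold). HMRA2 was listed at the floor of 0.1 TPM against 25.4 ± 2.95 TPM. The counts were 201 higher and 33 lower at 0 h, 797 and 459 at 12 h (638 and 570 with median-ratio scaling, shift 0.12), and 1104 and 329 at 16 h (629 and 686, shift 0.344).

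In coq2 rts1 several TCA cycle genes were higher than in coq2 at 16 h. SDH1 rose from 185 ± 0.0399 to 1240 ± 178 TPM, SDH2 from 619 ± 16.7 to 3630 ± 741, SDH4 from 876 ± 16.3 to 3890 ± 873 and ACO1 from 39.4 ± 0.766 to 258 ± 25.9 TPM, among 8 of 15 genes of the list (adjusted p = 0.054). ATP synthase genes were higher in 8 of 13 cases (6 with median-ratio scaling, adjusted p = 0.11) and glycolytic genes in 13 of 19 (ENO1 3.67-fold, PGK1 3.47-fold, TDH2 2.96-fold, TPI1 2.9-fold, adjusted p = 0.33). With quantile normalization 6 glycolytic genes were higher, and PGK1 and TPI1 fell just short of 2-fold. PET111, a translational activator of mitochondrial COX2 mRNA, rose from 1.75 ± 0.684 to 21.8 ± 5.32 TPM, SPG3 8.69-fold and CSM4 7.79-fold, and the heat shock gene SSA4 fell 5.39-fold and the checkpoint response gene HUG1 6.2-fold. ASP3-1 (YLR155C, chromosome XII, 469317 to 470405), an asparaginase gene with 3 identical neighbours, stood at 22.8 ± 8.34 against 5830 ± 91.2 TPM. It was low in all 6 coq2 rts1 libraries, and whether this strain still carries the locus was not analysed here, so the value is not assigned to the RTS1 deletion. At 0 h 16 of 34 general stress genes were higher (adjusted p = 0.0014). The counts were 127 higher and 87 lower at 0 h (195 and 48 with median-ratio scaling, shift -0.182), 404 and 461 at 12 h (493 and 372, shift -0.095), and 622 and 180 at 16 h (385 and 316, shift 0.192).

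In coq2 tco89 iron uptake genes were higher than in coq2 at 0 h, whereas in the single tco89 strain they were lower than in wt. Of 19 genes 7 rose over coq2 (adjusted p = 0.00014), with FIT3 at 3330 ± 160 against 613 ± 13.8 TPM, FIT2 at 7800 ± 261 against 2010 ± 165, ARN2 at 253 ± 3.2 against 66.2 ± 1.44 and ARN1 at 319 ± 11.6 against 125 ± 8.96 TPM. At 12 h 4 of 11 complex III genes were lower (7 with quantile normalization, adjusted p = 0.0063, or 0.069 on the 12 h libraries alone) and CYC1 was higher (log2 1.47). At 16 h 8 of 10 histone genes were higher (HTB1 3.39-fold, HTA2 3.28-fold, HHT1 3.23-fold, HHF1 2.98-fold, adjusted p = 0.32, 5 genes with median-ratio scaling), of which HHF1 has a 97.4% identical copy, HHF2, and is uncertain. The dicarboxylic amino acid permease gene DIP5 rose 8.71-fold, MEP2 8.2-fold and HRP1 7.39-fold, while NGL3 fell 7.67-fold, the methionine permease gene MUP3 7.33-fold and RRT15 6.84-fold. The counts were 42 higher and 17 lower at 0 h, 1225 and 169 at 12 h (403 and 444 with median-ratio scaling, shift 0.452), and 945 and 185 at 16 h (263 and 515, shift 0.448).

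In cox4 ras2 both stress and iron uptake genes were higher than in cox4 at 0 h. General stress genes were higher in 33 of 34 cases (adjusted p = 6e-05), with HSP26 at 2430 ± 47.1 against 33.8 ± 2.4 TPM, SIP18 53.5-fold, GND2 34.7-fold and HSP12 21.3-fold higher, as were 14 of 18 trehalose and glycogen genes (adjusted p = 0.0064, or 0.14 on the 0 h libraries alone). Iron uptake genes were higher in 12 of 19 cases (adjusted p = 0.01, or 0.05 on 0 h alone), FIT3 at 4010 ± 215 against 86.3 ± 8.78 TPM, FIT2 at 6930 ± 184 against 372 ± 35.9, ARN2 6.01-fold and TIS11 5.81-fold higher. Ribosome biogenesis genes were lower in 67 of 89 cases (NOP1 2.77-fold, NOP7 2.68-fold, UTP23 2.52-fold, DBP2 2.51-fold, adjusted p = 0.13). At 12 h complex III genes were lower in 8 of 11 cases (adjusted p = 0.0067, or 0.095 on 12 h alone). At 16 h cytosolic ribosomal protein genes were higher in 97 of 133 cases (RPL43B 4.74-fold, RPL24A 4.71-fold, RPL4B 4.31-fold, RPL18B 3.97-fold, adjusted p = 0.22). HXT13 rose from 17.2 ± 0.764 to 510 ± 12.5 TPM, HXT17 27.1-fold and DSF1 8.9-fold, and BTN2 fell 19.4-fold, SSA4 11.4-fold and CIS3 10.7-fold. The counts were 348 higher and 230 lower at 0 h, 487 and 422 at 12 h, and 622 and 412 at 16 h.

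The cox4 rts1 strain, with 1 library at 16 h, held more of several TCA cycle transcripts than cox4 at that time. SDH2 stood at 4370 TPM against 642 ± 1.18 in cox4, SDH1 at 1280 against 220 ± 5.78, ACO1 at 243 against 41.8 ± 1.86 and SDH4 at 4240 against 884 ± 42 TPM, among 9 of 15 genes higher (adjusted p = 0.08). In the glyoxylate and gluconeogenesis list 4 of 12 genes were higher and ADH2 was lower, and the list did not stand apart (adjusted p = 0.5). PCK1 was 9.61-fold, PET111 8.3-fold and SPG3 8.06-fold higher, and SSA4 was 8.71-fold, RGI1 6.57-fold and BTN2 6.51-fold lower. Glycolytic genes were higher in 16 of 19 cases at 12 h (adjusted p = 0.036, or 0.11 on the 12 h libraries alone), with PYK2 lower (log2 -1.07), and general stress genes in 20 of 34 at 0 h (adjusted p = 0.0002). The counts were 112 higher and 74 lower at 0 h (157 and 45 with median-ratio scaling, shift -0.173), 276 and 706 at 12 h (600 and 262, shift -0.362), and 653 and 290 at 16 h (477 and 413, shift 0.142).

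The cox4 tco89 strain differed from cox4 in fewer genes than the other cox4 double mutants did. At 16 h 1 of its libraries held COX4 transcripts, and whether it is mixed was not analysed here. Without it 754 genes passed, against 715. At 0 h complex III genes were higher (2 of 11 past the threshold, 0 with median-ratio scaling, adjusted p = 0.00024) and genes under nitrogen catabolite repression were lower (4 of 23, adjusted p = 0.008). At 16 h 7 of 10 histone genes were higher (HTA2 4.13-fold, HTB2 3.25-fold, HHF1 2.56-fold, HTA1 2.49-fold, adjusted p = 0.088), of which HTA1 fell short of 2-fold with quantile normalization. Iron uptake genes were lower in 9 of 19 cases (adjusted p = 0.15), with FIT3 at 7140 ± 70.9 against 41100 ± 2070 TPM, FRE2 4.39-fold, FIT1 3.14-fold and ARN2 3.07-fold lower, of which FIT1 fell short of 2-fold with a pseudocount of 5. HXT2 rose 4.04-fold and PHS1 3.94-fold, and HUG1 fell 9.92-fold and LSO1, of the iron response, 8.13-fold. HMRA2 was listed at the floor of 0.1 TPM against 58.3 ± 19.2 TPM. The counts were 45 higher and 22 lower at 0 h (33 and 28 with median-ratio scaling, shift 0.091), 156 and 244 at 12 h, and 187 and 528 at 16 h (415 and 292, shift -0.269).

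At 16 h part of the genes called in each electron transport chain mutant changed past the threshold in the direction of wt in its double mutants. These are said to have moved back, and they include genes that went beyond the wt level, which were not counted apart. The mean log2 level of the cytosolic ribosomal protein genes, relative to wt at 0 h, was -3.16 in coq2 and -2.58 in wt. It was -1.29 in coq2 ras2, -2.98 in coq2 rts1 and -2.30 in coq2 tco89. Of the 790 genes called in coq2, 48.4% moved back past the threshold in coq2 ras2, 27% in coq2 rts1 and 51% in coq2 tco89, and 0.886%, 1.01% and 0.38% moved further the same way. For the 664 genes called in cox4 the shares were 37.7% in cox4 ras2, 34.5% in cox4 rts1 (n = 1) and 18.2% in cox4 tco89, with 1.66%, 1.2% and 3.01% moving further. These shares are on the deposited scale, and the genes they count depended on it. In coq2 78 were higher and 712 lower, against 308 and 188 with median-ratio scaling. In cox4 these were 115 and 549, against 298 and 203. The other shares stayed within 1.5 times of the reported value with the alternatives, but that in cox4 tco89 did not. The share in cox4 tco89 was 28.1% with median-ratio scaling and 29.3% with CUP1-1 left out. It covered 53.9% of the genes higher in cox4 and 10.7% of those lower, against 62.6% and 32.4% in cox4 ras2 and 40.9% and 33.2% in cox4 rts1, and the shares in the coq2 double mutants were alike in both directions (52.6% and 47.9%, 26.9% and 27%, 51.3% and 51%). Independent lists would give 17.8%, 10%, 15.1%, 10.2%, 10.2% and 4.27% moved back in that order. Simulated double mutants with no effect gave 0%, which follows from their having almost no calls. With each deletion's effects dealt out at random over genes, simulations gave 18.9%, 11.4%, 17.1%, 11.7%, 11.9% and 5.66% with the single-mutant libraries shared by both comparisons, and 17.8%, 10.5%, 15.8%, 10.6%, 11% and 4.95% with separate ones. Part of the excess may come from the shared libraries. Against wt, the genes still past the threshold the same way were 16.5%, 25.9% and 12.9% of the coq2 genes and 25.6%, 24.8% and 48% of the cox4 genes.

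**Figure D2:**
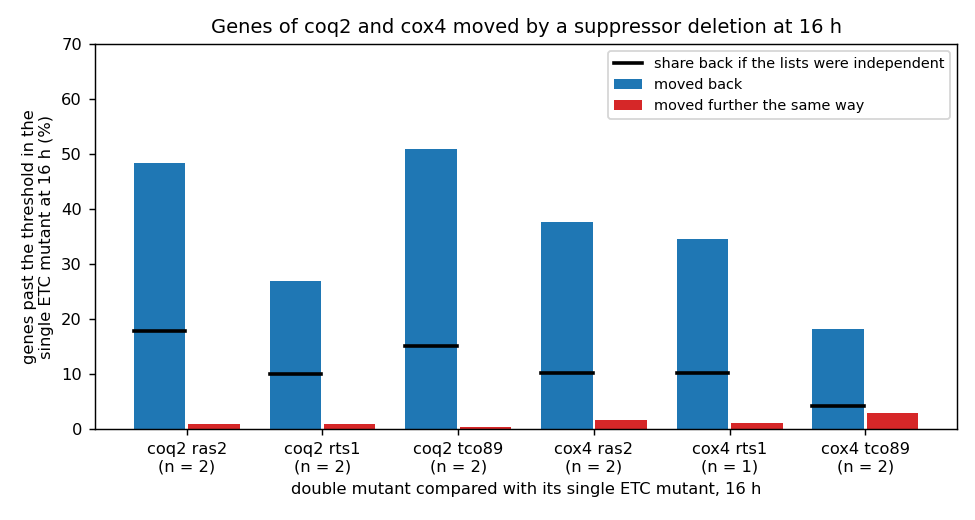
Share in percent of the genes past the threshold in coq2 or cox4 at 16 h that changed in the direction of wild type (blue) or further the same way (red) in each double mutant. Blue includes genes that went beyond the wild-type level. The black line is the share independent lists would give. The blue bars ran from 18.2% in cox4 tco89 (28.1% with median-ratio scaling) to 51% in coq2 tco89.

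The genes that moved back differed by list. Of the 11 TCA cycle genes lower in coq2, 5 moved back with RTS1 deleted (ACO1, IDH2, KGD2, SDH1 and SDH3), 3 with TCO89 and 1 with RAS2 deleted. The same 5 of 10 moved back in cox4 rts1, 4 in cox4 ras2 and 0 in cox4 tco89. ATP synthase genes moved back in 8 of 11 cases in coq2 rts1 and 6 of 11 in cox4 rts1, against 2 of 11 in each ras2 double mutant, and 1 of 11 in coq2 tco89 and 2 of 11 in cox4 tco89. Of the 11 glyoxylate genes lower in coq2, 4 moved back in coq2 ras2 (ICL1, MLS1, SFC1 and JEN1), 4 in coq2 rts1 (CIT2, PCK1, SFC1 and JEN1) and 2 in coq2 tco89 (MLS1 and MDH2). Of 10 in cox4, 2 moved back in cox4 ras2 (PCK1 and JEN1), 4 in cox4 rts1 (FBP1, PCK1, SFC1 and JEN1) and 1 in cox4 tco89 (CIT2), and ADH2 in cox4 rts1 and ICL1 and FBP1 in cox4 tco89 moved further down. Differences between these counts were not tested, and the counts depended on the scaling. With median-ratio scaling 7 TCA cycle and 5 ATP synthase genes were lower in coq2, and 5 and 5 in cox4. In coq2 rts1 6 of 13 ATP synthase genes were then higher than in coq2, and 4 with quantile normalization. In cox4 rts1 (n = 1) that list's median log2 change from cox4 was 0.99, or 0.84 and 0.62 with these scalings. In the single rts1 strain 5 of 15 TCA cycle genes were also higher than in wt at 16 h.

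CUP1-1 took a large and variable part of the libraries. Its mean share of the TPM in wt was 0.241% at 0 h, 5.44% at 12 h and 5.72% at 16 h, against 0.36%, 16.2% and 18.6% in coq2 and 0.406%, 15.4% and 20% in cox4. The single suppressor strains held 1.98% (ras2), 1.94% (rts1) and 3.26% (tco89) at 16 h. The double mutants stood between, at 6.84%, 4.02% and 4.4% in coq2 ras2, coq2 rts1 and coq2 tco89 and at 7.13%, 3.58% and 9.78% in cox4 ras2, cox4 rts1 and cox4 tco89.

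**Figure D3:**
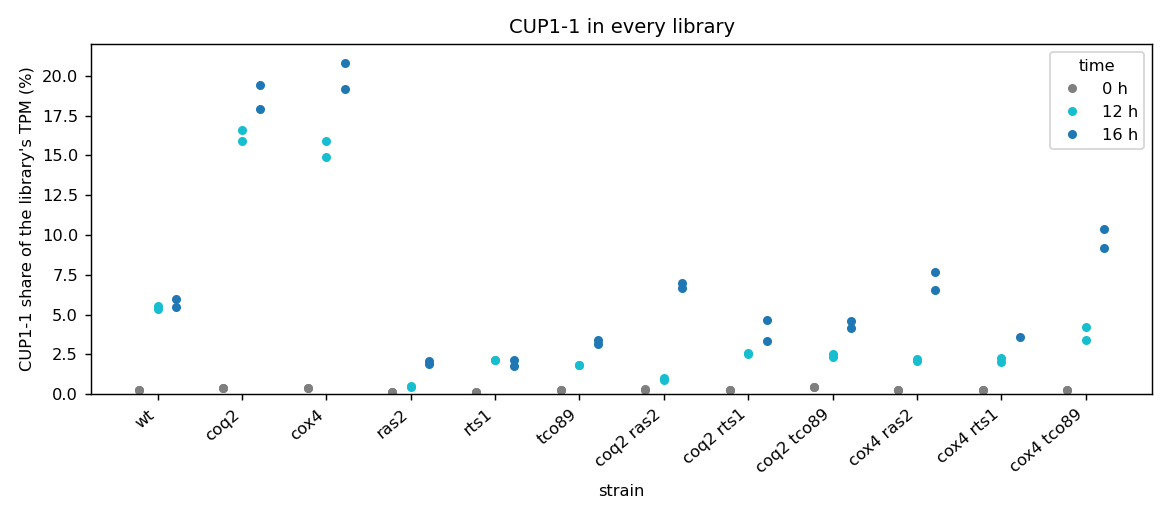
Share of each library's TPM taken by CUP1-1, in percent, by strain, with 1 point per library and colors for 0, 12 and 16 h. The coq2 and cox4 libraries at 12 and 16 h lie above all others, with group means of 15.4% to 20%.

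**Figure D4:**
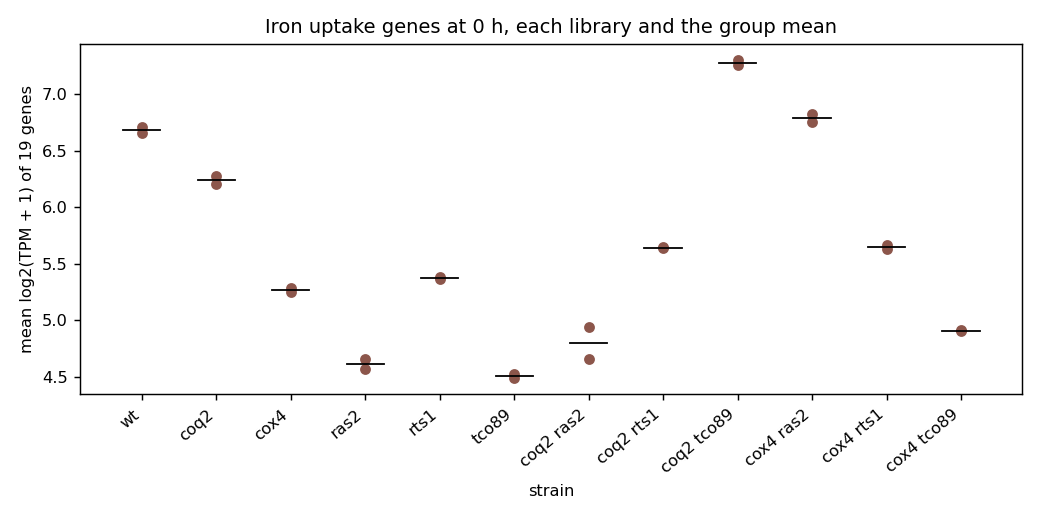
Mean log2(TPM + 1) of the 19 iron uptake genes at 0 h by strain, with 1 point per library and a bar for the group mean. Group means ran from 4.51 in tco89 to 7.28 in coq2 tco89, and libraries of a group differed by at most 0.28.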

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

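The tests below on CUP1-1, on the scaling of the glyoxylate genes and on the iron uptake genes were chosen only after the results were seen. The changes over time and the iron uptake genes stood out because an effect differed between strains by an interaction test, and the balance of lower and higher genes was taken up for its dependence on the scaling.

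The change from 0 to 16 h differed from that of wt for 816 genes in coq2 and 756 in cox4. The genes below come from those already named for wt at 16 h against 0 h and for the mutant against wt at 16 h. They were thus chosen on the same 16 h libraries, and the values below are no separate support for those differences. In coq2 the log2 change minus that of wt was negative for ECM13 (-6.33), SFC1 (-5.41), ICL1 (-4.70), MLS1 (-4.56), FBP1 (-3.89), IDP2 (-3.84), PCK1 (-3.68) and JEN1 (-3.35), and positive for RRT15 (4.43), PHO89 (2.31), CIS3 (2.09), SCW4 (1.92), BTN2 (1.69), ZPS1 (1.36), CUP1-1 (1.13) and SFG1 (1.03), which fell in wt and fell less in coq2. In cox4 the difference was negative for ECM13 (-5.65), SFC1 (-5.06), ICL1 (-4.50), PCK1 (-3.59), FBP1 (-3.58), IDP2 (-3.56), MLS1 (-3.48) and SIP4 (-3.21), and positive for HXT13 (3.08), PHO89 (2.52), DSF1 (2.24), CIS3 (2.14), SCW4 (2.02), BTN2 (1.91), ZPS1 (1.73) and SUC2 (1.61). CUP1-1, HXT13 and DSF1 are uncertain because of their near copies.

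Lower genes outnumbered higher ones in the electron transport chain mutants at 16 h, at 90.1% of the calls in coq2 and 82.7% in cox4. With CUP1-1 left out and the other genes rescaled, lower genes made up 68.3% and 51.8%, and with median-ratio scaling 37.9% and 40.5%. A larger share of CUP1-1 and other abundant transcripts and a true fall of many genes cannot be told apart, since TPM holds no absolute amount and the share left after removing CUP1-1 lay above the bound set for coq2. Such a shift is argued against as the cause of the falls of the glyoxylate and gluconeogenesis genes, whose median log2 change with median-ratio scaling was -2.56 in coq2 (adjusted p = 0.0031) and -2.52 in cox4 (adjusted p = 0.0053). The call of that list was lost on the 16 h libraries alone with the deposited scaling (adjusted p = 0.095 and 0.099), so this rests on the medians, and no biological explanation was tested.

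CUP1-1 itself was higher in both mutants at 16 h. A fixed difference in the number of copies would give the same ratio to wt at every time, but the log2 ratio at 16 h exceeded that at 0 h by 1.13 ± 0.15 (SE, adjusted p = 8.5e-08) in coq2 and 1.05 ± 0.15 (SE, adjusted p = 3.8e-07) in cox4, which argues against it as the whole cause. A smaller part from copy number could remain, as the ratios at 0 h were already 0.58 and 0.75. Regulation by metal or stress was not tested.

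Iron uptake genes at 0 h were lower in ras2 and tco89 than in wt and higher in cox4 ras2 and coq2 tco89 than in the matching single mutants. The effect of the RAS2 deletion in cox4 minus that in wt passed the threshold for 16 of 19 genes (median log2 2.67), and that of TCO89 in coq2 minus that in wt for 18 (2.40). This restates the pattern and shows only that the levels in these libraries did not follow the suppressor deletion alone. For RAS2 in coq2 and TCO89 in cox4 2 and 14 genes passed (medians 0.50 and 1.37), and all 4 differences include the wt libraries at 0 h. A difference between cultures at sampling and an effect of the combined deletions cannot be told apart, because the labels give technical replicates only: libraries of a group differed by at most 0.28 in mean log2 level, against group means of 4.51 to 7.28, and separate cultures of a strain might differ by more.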

How the results depend on the processing

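The alternative with CUP1-1 left out was chosen only after the data were seen, as was leaving out the cox4 tco89 library with COX4 transcripts. No paired analysis was possible because the columns of the table carry no replicate number, so the planned replicate block was not run. Read depth is unknown for TPM, so limits of detection cannot be given, and groups of 2 technical replicates allow no test of other groupings. For 297 pairs of named gene and comparison there were 3839 alternative values, of which 3820 kept direction and side of the threshold, 18 fell short of it and 1 reversed: CUP1-1 in coq2 at 16 h with quantile normalization, at log2 0, by construction, as the top-ranked gene of each library gets the same value. Of 600 values for 45 counts and shares 572 stayed within 1.5 times the reported value and 28 moved, and the cause was not tested. Without the cox4 tco89 library with COX4 transcripts 754 genes passed in cox4 tco89 at 16 h, against 715.

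With a pseudocount of 5, which shrinks changes of genes with low TPM, the counts were 144 for coq2 against wt at 12 h and 456 at 16 h, 29 for cox4 at 0 h and 386 at 16 h, 425 for rts1 at 16 h, 526 for coq2 rts1 against coq2 at 16 h, 912 and 726 for coq2 tco89 at 12 and 16 h, 671 for cox4 ras2 against cox4 at 16 h, 648 and 627 for cox4 rts1 at 12 and 16 h, 225 and 395 for cox4 tco89 at 12 and 16 h, and 485 and 476 for the changes over time of coq2 and cox4 minus that of wt. Median-ratio scaling gave 147 and 496 for coq2 at 12 and 16 h, 847 for coq2 tco89 at 12 h and 28.1% of cox4 genes moved back by tco89, and quantile normalization gave 150 and 479, and 847 and 742 for coq2 tco89 at 12 and 16 h. With CUP1-1 left out coq2 had 161 at 12 h and cox4 tco89 moved back 29.3%. Calls of gene lists numbered 107, against 44 with a fit on the time point alone, which has fewer residual degrees of freedom (42 of the 107 kept, 65 lost, all in the same direction), and 547 with a preset correlation of 0.01. In leave-one-out fits coq2 at 12 h ranged from 212 to 440 around 269, and every other count and share stayed within 1.5 times.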

Other observations

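All observations here were chosen after the values were seen, except the test of a straight line at 12 h. In log phase the 3 single suppressor strains shared a set of lower transcripts. Against wt at 0 h, 29 genes were lower in ras2, rts1 and tco89 alike and 11 were higher, where independent lists would share 0.0099 and 0.016. Simulations with the wt libraries shared gave 0 and 0 with no effect, which has almost no calls, and 0.12 and 0.05 on average (at most 2 and 2) with each strain's effects dealt out at random over genes, and part of the overlap may come from the shared wt libraries (QCR10 was 1 of the 11, and in tco89 it came to log2 0.88 without 1 of them). The lower genes included the iron permease and siderophore genes FTR1, ARN1, ARN2, ENB1, FIT2 and FIT3, the ferric reductase genes FRE1, FRE2 and FRE3, the phosphate transporter genes PHO84 and PHO89 with SPL2 and VTC3, and the zinc transporter gene ZRT1. The set was not particular to the suppressors, as 15 of the 29, with 10 of its 12 iron uptake genes, were also lower in cox4 than in wt at 0 h. Among the higher genes were QCR8, QCR10, SDH1, SDH2 and COX7 of the respiratory chain and ATP20 of ATP synthase, with YGL230C, YPS5, YHR054C, YJR120W and NCE103 as the others, and no list was tested on this overlap.

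ASP3-1, the asparaginase gene with 3 identical copies, was at 1.08 to 69.9 TPM in the 6 coq2 rts1 libraries and at 681 to 7670 TPM in the other 65. Whether the coq2 rts1 strain still carries the locus was not analysed here.

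A hypothesis set before the result was that the single suppressor strains at 12 h stood at an earlier point on a straight line from wt at 0 h to wt at 12 h. That line explained 18% of the variance over genes in ras2, 14.5% in rts1 and 27.8% in tco89, below the 80% needed in each for it to be the cause and not below 20% in each as needed to set it aside, so the test does not decide. Of the genes called against wt at 12 h, 516, 479 and 470 lay toward wt at 0 h, 67, 65 and 45 lay away from it, and 390, 500 and 175 were not called between the wt times. Both comparisons share the wt libraries at 12 h, and simulations that shared them and dealt each strain's effects out at random over genes gave 218, 222 and 189 toward and 249, 277 and 162 away. The median log2 change of the general stress genes was 0.33, -0.22 and 0.18. Their mean log2 level at 12 h, relative to wt at 0 h, was 4.56, 4.20 and 4.39, against 4.31 in wt. That of the glycolysis and fermentation genes was 0.22, 0.33 and 0.04, against -1.97 in wt. The former list thus stood near its wt level of 12 h and the latter near or above its wt level of 0 h. In tco89 the stress and glycolytic levels at 0 h were -0.15 and -0.65. There, for the genes of these lists, the values at 12 h argue against a single point on the line. In ras2 and rts1 the stress level at 0 h was already 2.54 and 0.99, so its level at 12 h does not place those cultures on the line. Their glycolytic level at 0 h was -0.22 and -0.08.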
